A study of Mus musculus with 20 samples.

How the data were processed

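The study sequenced poly(A)-selected RNA from the gastrocnemius muscle of male mice with a strand-marking (dUTP) kit, in 20 libraries: 5 each of controls, tetrathiomolybdate (TM), N-acetylcysteine (NAC) and both (TM+NAC); the treated groups are labelled 28 days. Groups were taken from the treatment label of each library. The authors deposited a single table of 31618 genes, and per the file headers it gives for each library a count and an FPKM value. The deposited count columns hold whole numbers that are not normalized. The deposited FPKM columns are scaled by length and depth. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9, checked with FastQC, aligned to GRCm38 with HISAT2 2.2.1 and assembled with StringTie. How counts were taken, whether strand was used and the annotation release are not given in the sources used here. The table was checked as follows. Over 795 genes with a single transcript, FPKM divided by count was constant apart from a factor per library, to within 0.169% (99th percentile). Of the gene IDs, 99.73% were found in GENCODE M21, and 90.79% of those had the same position. For 64 symbols more than 1 ID shared the symbol. The lowest correlation of log2 CPM between any pair of libraries was 0.948, and no pair within a group was so alike as to be the same library (lowest chi-square per degree of freedom 22.91).

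Library totals were 54.7 to 90.7 M counts, of which 98.23 to 98.69% fell in tested genes. Genes with a mean FPKM of at least 1 over the 20 libraries were tested, 9696 in all. Counts were scaled by the trimmed mean of M values (TMM) and fitted in a single edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3) of the 4 groups. Standard errors are the log2 fold divided by the square root of the F statistic. A two-sided test with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes was called passing, and a gene said to pass or not to pass without a named setting is judged by this fit on all libraries. The comparisons were TM with control, TM+NAC with TM, NAC with control, TM+NAC with NAC, TM+NAC with control, and the interaction, which is the TM effect with NAC minus the TM effect without it. The design written before the data were examined named limma on log2(FPKM + 1) for a file without counts and edgeR for one with counts. The test was tested on simulated data with changes added to 50 genes at each size, and it recovered 14% at the smallest size, 56% at 1.5-fold, 86% at 2-fold and 100% at 4-fold with 5 false calls in all.

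Of 54 gene lists fixed before the data were examined, 51 had at least 5 tested members and were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, adjusted over the 51 lists. The neutrophil, lymphocyte and skin lists had 3, 2 and 0 tested members. Beside each result stands camera with a correlation estimated for each list, and fry was run as well. Genes were named by a rule fixed before the data were examined: in each comparison the 10 with the smallest p among those passing in each direction, or, where none passed, the 3 with the smallest p, said not to pass. Genes without a symbol, predicted genes, clone names, pseudogenes and genes with a mean FPKM under 1 in both groups were left out of that choice. Up to 4 members of each list and a fixed set of 20 genes for copper, oxidative stress, atrophy, stress, iron and blood could be named in addition. Of that set, Atp7a (mean FPKM 0.286) and Gdf15 (0.0244) lay under the filter and were not tested, and Fgf21 was not analysed here. The separate results of some genes that the rule names are not reported here, and those genes stay in every fit, count and list.

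Lists of transcripts of other tissues were written after brain transcripts had been seen, for neurons (20 genes), astrocytes (12), oligodendrocytes (10), choroid plexus (12), peripheral nerve outside the brain (8), cartilage (15), inflamed stromal cells (13), liver (8), kidney (3), heart (7), lung (3), testis (4), the Y chromosome (4) and Xist. Most of the inflamed stromal genes were picked from the TM+NAC libraries. Libraries were divided into 13 with and 7 without brain transcripts at the largest gap in the sum of the neuron, astrocyte and oligodendrocyte genes, and the gene counts from this division and from TM+NAC were set beside 100 random sets of as many libraries, a check added after the result was seen. Alternatives planned before the data were examined were another pseudocount (0.1 with limma), no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, only the groups compared, a robust variance model, library weights with limma voom, a fold of at least 2 as well, the replicate number as a block, an exact rank-sum test and leaving out each library in turn. DESeq2 1.42.0, limma on log2(FPKM + 1), no TMM, brain transcripts as a term, only the libraries with brain transcripts, lists without the 22 TM+NAC genes, for gene lists, no filter and leaving out each library, and a division of the NAC libraries with 100 regroupings of the control, NAC and TM+NAC libraries were added after seeing the data. The planned share of TM genes with the same sign with NAC needs genes called after TM and was not computed. Each model was also refitted on 100 splits of the libraries, the real one included. Tables were handled with the R package data.table (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.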

Results

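RNA was measured in the gastrocnemius, a calf muscle, of male mice in 4 groups of 5 libraries: controls, tetrathiomolybdate (TM, a copper chelator), N-acetylcysteine (NAC, a thiol antioxidant) and both compounds together (TM+NAC). The labels of the treated groups give 28 days. Library totals ran from 54.7 to 90.7 M counts (M, 1e6 counts) with a median of 63.3 M, and levels are in counts per M (CPM), so a level of 1 stood for 63.3 counts at the median depth. The median standard error (SE) of a log2 fold between a pair of groups was 0.12 over 9696 tested genes. The labels number the libraries but do not say that each is a separate animal, so p-values measure the spread between these libraries, which may be technical. Folds are given as log2 ± SE and levels as mean CPM ± SD, with n = 5 libraries per group. Where not said otherwise, a count such as 5 of 5 is of libraries beyond the mean of the group compared with.

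Transcripts typical of brain tissue moved with the treated groups. The summed level of 20 neuronal genes was 10.5 ± 2.03 CPM in controls, 50.6 ± 21.8 in TM, 71.2 ± 34.9 in NAC and 80.4 ± 10.8 in TM+NAC. Among treated libraries, TM library 1 (12.2 CPM) and NAC library 4 (9.32 CPM) lay below the highest control (13.7 CPM), and the other 13 lay between 54.7 and 97.7 CPM. Snap25, which drives synaptic vesicle fusion, followed this division, at 1.37 ± 0.651 CPM in controls and 13 ± 2.24 in TM+NAC. Among genes of at least 0.5 CPM on average, 234 were over 1.5-fold higher in each of these 13 libraries than in any of the remaining 7, and 0 were lower in the same way. For a division fixed in advance, and with no fold asked for, chance would put 13 libraries above the other 7 in 0.00129% of genes. The same criteria gave 0 genes in each of 100 random sets of 13 libraries, but the division itself was drawn from the summed brain genes. The 234 genes are called the brain-pattern genes from here on. They took 0.0446 to 0.0803% of counts in the 13 libraries and 0.00645 to 0.00928% in the 7.

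A further set of 22 genes, of at least 0.5 CPM in TM+NAC, was over 1.3-fold higher in all 5 TM+NAC libraries than in any other library, and 0 genes set TM, NAC or controls apart in this way. With no fold asked for, chance would put 5 given libraries above the other 15 in 0.00645% of genes, and the same criteria gave at most 1 gene in 100 random sets of 5 libraries. Besides Lox, Thbs1 and Fn1, it held Col2a1, the main collagen of cartilage, at 16 ± 3.13 CPM in TM+NAC and 0.885 ± 1.37 in controls. Mmp3, a matrix-degrading protease, was at 7.06 ± 4.02 CPM in TM+NAC and 0.202 ± 0.0868 in controls. Saa3, an acute-phase protein, was at 6.53 ± 4.45 CPM in TM+NAC and listed at 0 in every control. Xist, the RNA of the inactive X chromosome of females, was at 1.22 to 3.22 CPM in TM+NAC and at most 0.859 elsewhere. Transcripts of 4 Y-linked genes together were at 130 to 234 CPM in every library. Snap25, Col2a1, Mmp3, Saa3 and Xist were chosen after their values were seen.

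**Figure D1:**
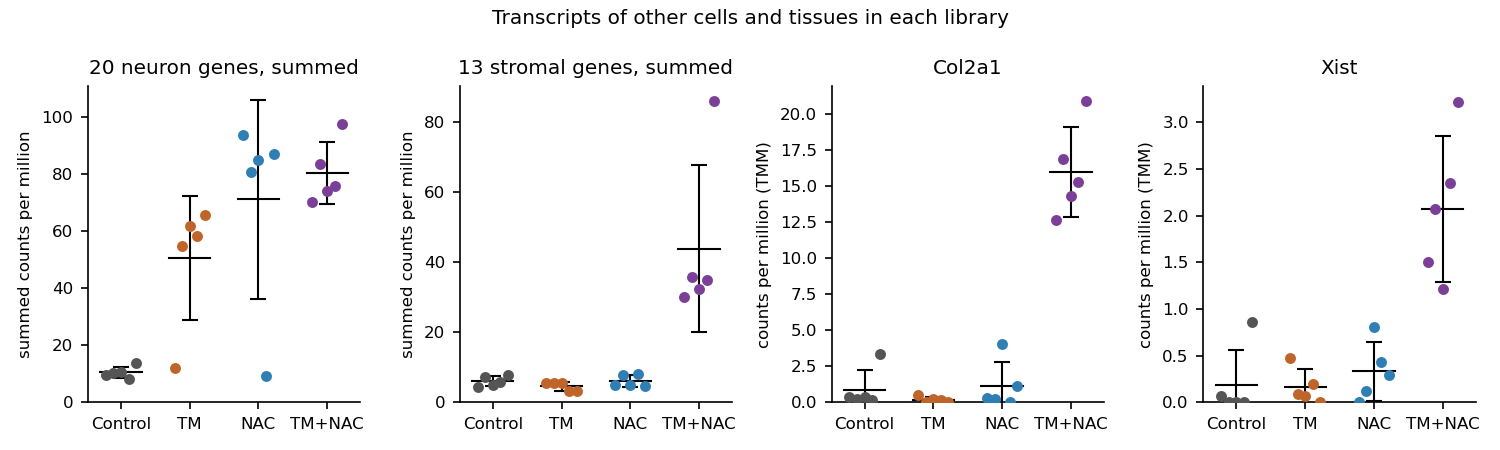
Summed CPM of 20 neuronal genes and of 13 genes of inflamed stromal cells, with Col2a1 and Xist, by group (dots are libraries, the line is the mean and the bar the SD, n = 5). TM library 1 and NAC library 4 lie with the controls in the neuronal panel at 12.2 and 9.32 CPM, and the 5 TM+NAC libraries lie above all others in the remaining panels. Col2a1 and Xist were chosen for lying so, and most of the 13 stromal genes were picked from these libraries. Those panels are therefore no separate evidence.

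After TM alone, no gene past the filter on low values passed the test against controls. Nmrk2, a kinase that feeds nicotinamide riboside into NAD synthesis, had the smallest p. It was at 149 ± 33.3 CPM after TM and 58.2 ± 14.6 in controls, a log2 fold of 1.35 ± 0.23, higher in 5 of 5 libraries (adjusted p = 0.071, not passing). Pcca, a subunit of propionyl-CoA carboxylase, had a log2 fold of 0.35 ± 0.06, higher in 5 of 5 (adjusted p = 0.071, not passing). The smallest p among lower genes were those of Atcay at -1.02 ± 0.24, Mybph, a myosin-binding protein, at -1.07 ± 0.27, and Ppp1r10 at -0.40 ± 0.11, and none passed. With edgeR, 0 of 9696 genes passed, 327 had an unadjusted p under 0.05 where 485 are expected by chance, DESeq2 called 19 and limma on log2(FPKM + 1) called 1. With no filter on low values edgeR called 197, 196 higher and 1 lower, of which 120 were brain-pattern genes.

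None of the copper genes tested passed after TM. Slc31a1, the cell's copper importer, was at 0.03 ± 0.09, Ccs, which loads copper into superoxide dismutase, at -0.14 ± 0.14, and Sod1 itself at -0.07 ± 0.08. The metal-binding metallothioneins Mt1 and Mt2 were at -0.14 ± 0.25 and 0.06 ± 0.34. Of the copper uptake, chaperone and export list, 0 of 21 members passed, over all genes or adjusted over the list alone. Among oxidative stress genes, Hmox1 (haem oxygenase) was at 0.23 ± 0.13, Nqo1 (quinone reductase) at -0.11 ± 0.11, Gclc (glutathione synthesis) at 0.07 ± 0.10 and Txnrd1 (thioredoxin reductase) at 0.09 ± 0.10. The atrophy ligases Fbxo32 and Trim63 were at 0.05 ± 0.27 and 0.08 ± 0.16, and Mstn, which restrains muscle growth, at 0.00 ± 0.17. The adjusted p of each of these genes was 0.999.

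Among 51 gene lists, camera called 4 after TM against controls. Cytosolic ribosomal proteins were lower as a list (48 of 49 with negative folds, median -0.107, camera adjusted p = 1.3e-06), and adipocyte markers, among them the lipid desaturase Scd1 at -0.97 ± 0.41, were lower (12 of 13 negative, median -0.241, adjusted p = 0.000166). Both had an adjusted p = 0.867 with an estimated correlation. Antigen presentation was lower (10 of 13 negative, adjusted p = 0.0288, and 0.867 as the adjusted p with an estimated correlation). Immediate early genes were higher (17 of 21 positive, adjusted p = 0.0358, and 0.867 as the adjusted p with an estimated correlation). No member of these 4 lists passed over all genes or adjusted over the list alone (0 by edgeR). The single member to pass over a list alone was Nmrk2 in the atrophy programme.

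Without TM library 1, edgeR called 12 genes, all higher, of which 10 were brain-pattern genes and the others Nmrk2 (adjusted p = 0.0146) and Pcca, and DESeq2 on all libraries called Nmrk2 at an adjusted p of 0.000304 and 12 brain-pattern genes among its 19. Antigen presentation was lost without Control 1, 2 or 5 or TM 3 or 5 (adjusted p = 0.132, 0.193, 0.102, 0.199 and 0.0995), immediate early genes were lost without Control 1, 3 or 4 or TM 2 (0.521, 0.15, 0.285 and 0.565), and the 4 lists became 12, 11 and 7 without Control 3, 4 and 5 and 8, 7, 13 and 10 without TM 1, 3, 4 and 5.

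**Figure D2:**
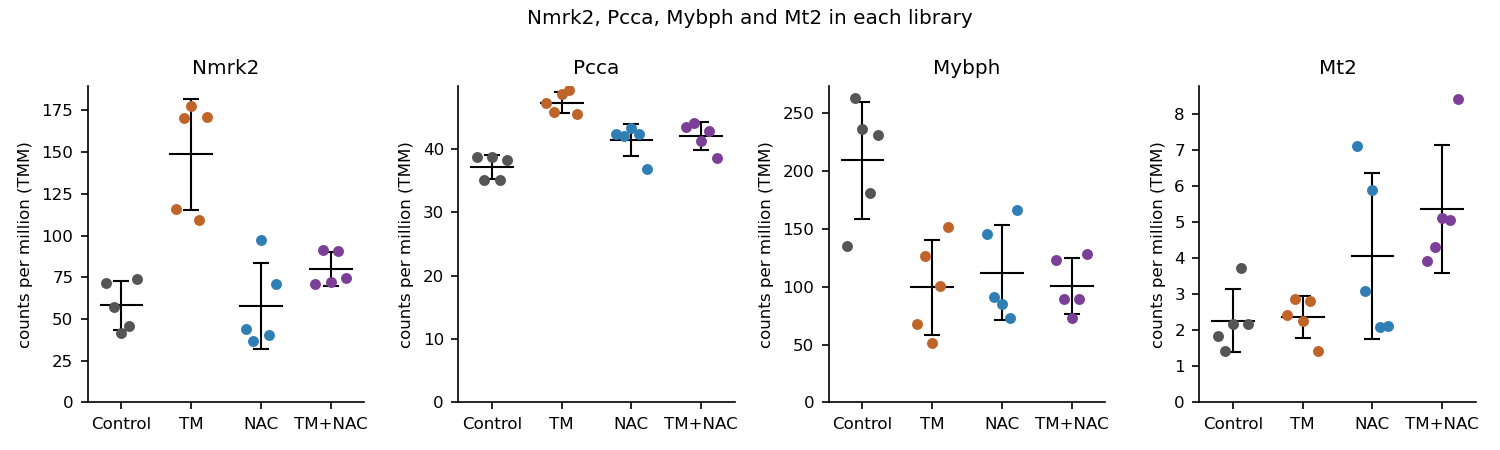
CPM of Nmrk2, Pcca, Mybph and Mt2 by group (dots are libraries, the line is the mean and the bar the SD, n = 5). Nmrk2 averaged 149 CPM after TM against 58.2 in controls and 79.9 in TM+NAC.

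TM+NAC differed from TM alone in 3 matrix genes. Lox, the copper-dependent enzyme that cross-links collagen and elastin, rose from 6.76 ± 2.39 CPM in TM to 43.6 ± 13.8 in TM+NAC, a log2 fold of 2.69 ± 0.28 (adjusted p = 4.81e-05). Thbs1, a secreted glycoprotein that activates TGF-beta, rose from 8.33 ± 4.31 to 48.6 ± 10.4 CPM, by 2.54 ± 0.35 (adjusted p = 0.00172). Fn1, fibronectin, rose by 1.24 ± 0.17 (adjusted p = 0.00172). Each of the 3 was higher in 5 of 5 TM+NAC libraries than in any other library of the study. All 3 belong to the 22 genes that stood above every other library in TM+NAC, beside Col2a1, Saa3 and Xist.

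The fibrillar collagen and matrix list was higher in TM+NAC than in TM (25 of 28 folds positive, median 0.241). Of its members 3 passed, and 5 adjusted over the list alone (camera adjusted p = 1.88e-17, and 0.436 as the adjusted p with an estimated correlation). Timp1, an inhibitor of matrix proteases, was at 3.36 ± 0.66 (adjusted p = 0.075, not passing, higher in 5 of 5, and passing with DESeq2 at 0.0127). Copper-dependent enzymes were called higher through Lox, the 1 of 13 members to pass, over all genes and adjusted over the list alone (adjusted p = 0.0215, and 0.23 as the adjusted p with an estimated correlation). The mean of this list was 0.269 and its median 0.0378, and without the 22 genes its adjusted p was 0.674. The 13 protein-coding genes of the mitochondrial genome were lower as a list, all negative with a median of -0.253 (adjusted p = 2.2e-07, and 0.624 as the adjusted p with an estimated correlation). Among them, mt-Atp6, an ATP synthase subunit, was at -0.34 ± 0.13, and 0 of 13 passed by edgeR.

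Nerve and Schwann cell markers were higher (9 of 9 positive, camera adjusted p = 5.73e-06, and 0.616 as the adjusted p with an estimated correlation), among them the myelin gene Mbp at 0.88 ± 0.39, and 0 of 9 passed. The neuronal sum was 50.6 CPM in TM and 80.4 CPM in TM+NAC. Ribosomal proteins were higher (48 of 49 positive, adjusted p = 8.43e-06, and 0.821 as the adjusted p with an estimated correlation). ER stress genes were higher, with the chaperone Hspa5 at 0.16 ± 0.08 (21 of 26 positive, adjusted p = 0.00246, and 0.23 as the adjusted p with an estimated correlation). NRF2 targets were higher, with Hmox1 at 0.39 ± 0.13 (20 of 29 positive, adjusted p = 0.0262, and 0.582 as the adjusted p with an estimated correlation). The integrated stress response was higher (12 of 17 positive, adjusted p = 0.0459, and 0.436 as the adjusted p with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone (0 by edgeR). Outside the matrix, Mt1 and Mt2 had folds of 0.77 ± 0.25 and 1.18 ± 0.33 (adjusted p = 0.64 and 0.51), and Nmrk2 of -0.90 ± 0.23 (adjusted p = 0.442), none passing.

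With edgeR, 3 of 9696 genes were higher and 0 lower (503 at an unadjusted p under 0.05, and 21 called with no filter), DESeq2 called 7 higher and 12 lower, limma on log2(FPKM + 1) called 6, and the fit of only the libraries with brain transcripts called 9, with Lox, Thbs1 and Fn1 among them. Calls on lists were lost without TM 4 or 5 or TM+NAC 3 for copper-dependent enzymes (adjusted p = 0.0854, 0.126 and 0.05), without TM 3 for NRF2 targets (0.0922), without TM 1, 3 or 4 or TM+NAC 3 or 5 for the integrated stress response (0.0618, 0.115, 0.0647, 0.136 and 0.0606), and under quantile normalization for the mitochondrial genome (0.326).

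**Figure D3:**
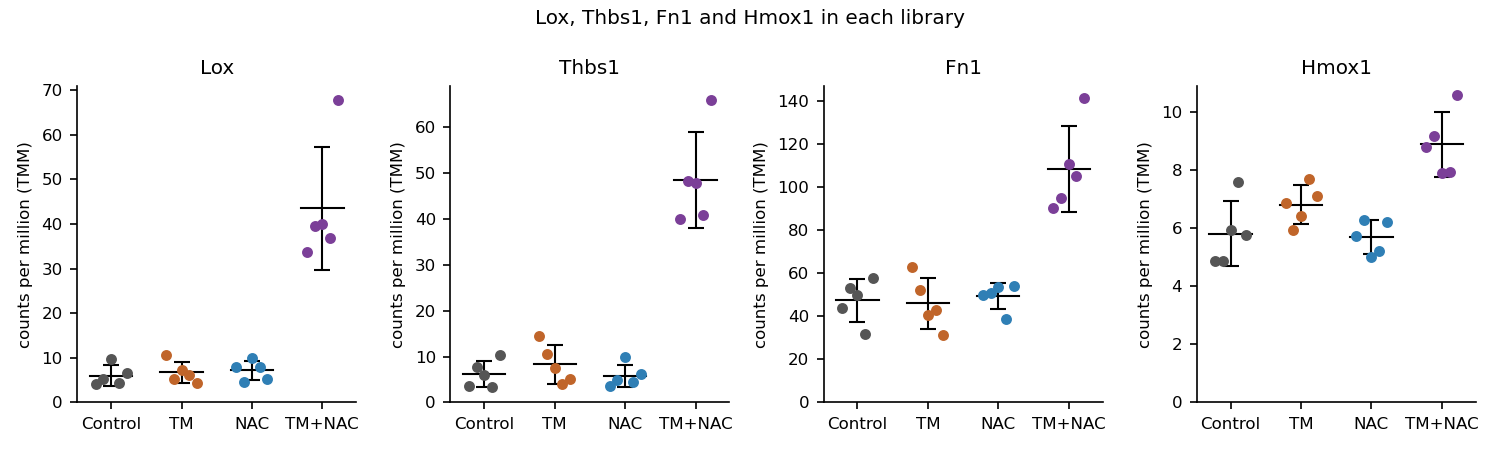
CPM of Lox, Thbs1, Fn1 and Hmox1 by group (dots are libraries, the line is the mean and the bar the SD, n = 5). Lox lies between 33.7 and 67.8 CPM in the TM+NAC libraries and at 10.6 or less in the other 15.

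After NAC alone, most genes that rose belonged to the brain-pattern genes. Kif5a, a neuronal kinesin, rose by 4.09 ± 0.67 (adjusted p = 0.0104) and Ndrg4, abundant in neurons, by 2.14 ± 0.35 (adjusted p = 0.0104). Gpm6a, a neuronal membrane glycoprotein, rose by 2.27 ± 0.35 (adjusted p = 0.0102) and the noncoding RNA Snhg11 by 4.48 ± 0.71 (adjusted p = 0.0104). Each of these 4 genes was above every control in 4 of 5 NAC libraries, and NAC library 4 was not. Meg3, an imprinted noncoding RNA, rose by 1.08 ± 0.16 in 5 of 5 (adjusted p = 0.0102). Of 20 genes that rose and 1 that fell (the predicted gene Gm14586), 14 were brain-pattern genes, and Ndrg4 and Meg3 were not among these.

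Genes of mitochondrial energy metabolism were lower as lists after NAC, although no member passed over all genes or adjusted over the list alone (0 by edgeR). Complex I, which feeds electrons from NADH into respiration, had 35 of 36 members with negative folds and a median of -0.291 (camera adjusted p = 1.77e-15), with Ndufa12 at -0.62 ± 0.19 and Ndufa10 at -0.25 ± 0.09. The ATP synthase list was negative in 16 of 16 members (median -0.202, adjusted p = 1.34e-06), with Atp5l at -0.28 ± 0.09. Nuclear-encoded complex IV was negative in 24 of 28 (adjusted p = 2.04e-06), complexes II and III in 14 of 16 (adjusted p = 5.31e-05) and the TCA cycle in 16 of 18 (adjusted p = 0.000527). Fatty acid oxidation was negative in 23 of 28 (adjusted p = 1.28e-05), with Cpt1b, the muscle carnitine transferase, at -0.22 ± 0.08. Antioxidant enzymes were negative in 27 of 32 (adjusted p = 0.00246), with the secreted peroxidase Gpx3 at -0.46 ± 0.14, and haem synthesis in 11 of 13 (adjusted p = 0.0106). Each of these 8 lists had an adjusted p = 0.428 with an estimated correlation. NAC library 4 had 20.3% of counts from mitochondrial genes against 13.6 to 15.4% in the other 4 NAC libraries, and without it 9 of the 10 lower lists were still called. The complex I median of 3 NAC libraries against controls was -0.287 to -0.48 with NAC 4 among them and -0.112 to -0.219 without it.

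Ribosomal proteins were lower after NAC (47 of 49 negative, median -0.155, camera adjusted p = 2.65e-07, and 0.652 as the adjusted p with an estimated correlation). Slow-twitch fibre genes were lower (16 of 17 negative, median -0.298, adjusted p = 0.000666, and 0.636 as the adjusted p with an estimated correlation), with the stretch-responsive Ankrd2 at -0.61 ± 0.25. Higher lists were glucocorticoid-responsive genes, with the kinase Sgk1 at 0.62 ± 0.15 (15 of 24 positive, adjusted p = 0.00578, and 0.588 as the adjusted p with an estimated correlation), and the collagen and matrix list (25 of 28 positive, adjusted p = 0.00578, and 0.903 as the adjusted p with an estimated correlation). Nerve markers were higher beside the neuronal sum of 71.2 CPM (9 of 9 positive, adjusted p = 0.00578, and 0.652 as the adjusted p with an estimated correlation). The circadian clock was higher, with Per1 at 0.64 ± 0.26 (14 of 19 positive, adjusted p = 0.0269, and 0.428 as the adjusted p with an estimated correlation). Of these lists, nerve markers apart, 0 members passed over all genes by edgeR, and 1 glucocorticoid-responsive gene passed adjusted over the list alone. Mt2 was at 0.84 ± 0.33, Nqo1 at 0.21 ± 0.11, Hmox1 at -0.03 ± 0.13 and Gclc at 0.12 ± 0.10, with adjusted p of at least 0.638.

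Kif5a was lost without Control 1 (adjusted p = 0.0619), and the 21 calls (721 at an unadjusted p under 0.05, 488 without NAC 4) became 4, 8, 9, 7 and 10 without Control 1 to 5 in turn, 5, 15, 5 and 5 without NAC 1, 2, 3 and 5, 41 without NAC 4 (16 of them brain-pattern genes), 439 with no filter (209 of them brain-pattern genes), 38 with DESeq2, 2 with limma on log2(FPKM + 1), 0 with only the groups compared, and 2322 (1134 higher and 1188 lower, 4 of them among the 21) with brain transcripts as a term, which rests on TM 1 and NAC 4 alone. Calls on lists were lost without Control 1 or NAC 3 for glucocorticoid-responsive genes (adjusted p = 0.129 and 0.17) and nerve markers (0.156 and 0.17), without Control 4, where the direction turned, or NAC 3 for collagen and matrix (0.865 and 0.144), without Control 1, 2 or 5 or NAC 1 or 2 for the clock (0.0531, 0.191, 0.0877, 0.0586 and 0.0716), and without NAC 4 for haem synthesis (0.06).

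Lox, Thbs1 and Fn1 were also the 3 genes called between TM+NAC and NAC alone. Lox rose from 7.17 ± 2.22 CPM in NAC to 43.6 ± 13.8 in TM+NAC, by 2.60 ± 0.28 on the log2 scale (adjusted p = 7.78e-05). Thbs1 rose from 5.81 ± 2.46 to 48.6 ± 10.4 CPM, by 3.06 ± 0.36 (adjusted p = 0.000173), and Fn1 rose by 1.13 ± 0.17 (adjusted p = 0.00592). Each was higher in 5 of 5 libraries. Hmox1, which degrades haem, was at 8.89 ± 1.11 CPM in TM+NAC and 5.69 ± 0.577 in NAC, higher in 5 of 5, a fold of 0.64 ± 0.13 (adjusted p = 0.132, not passing, and 0.00165 with DESeq2). The smallest p among lower genes was that of Sh3bp5 at -0.36 ± 0.08 (adjusted p = 0.359, not passing).

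Of the 10 lists lower in NAC than in controls, 8 were called higher in TM+NAC than in NAC, ribosomal proteins among them. Complex I had 35 of 36 positive folds (median 0.269, camera adjusted p = 5.83e-12), ATP synthase 16 of 16 (adjusted p = 1.73e-05), fatty acid oxidation 21 of 28 (adjusted p = 1.73e-05) and complex IV 23 of 28 (adjusted p = 7.7e-05). Complexes II and III had 13 of 16 (adjusted p = 0.00045), antioxidant enzymes 26 of 32 (adjusted p = 0.00328) and the TCA cycle 15 of 18 (adjusted p = 0.0157). Heat shock proteins, a list not called in NAC against control, were higher with 14 of 19 (adjusted p = 0.0209). These 7 lists and heat shock proteins had an adjusted p = 0.468 with an estimated correlation. Examples were Ndufb10 of complex I at 0.34 ± 0.14, Atp5l at 0.28 ± 0.09 and the dehydrogenase Hadh at 0.23 ± 0.07. No member of them passed over all genes or adjusted over the list alone (0 by edgeR). Because the same 5 NAC libraries enter both comparisons with opposite sign, lists turn with no group effect too: 12 of the 14 lists called in NAC against control (85.7%) had the opposite direction here, against 83.9% in 100 regroupings of the control, NAC and TM+NAC libraries, and 8 (57.1%) were called in it, against 43.6%, a share that 30 of the 100 regroupings reached. With the NAC libraries divided between the comparisons in 10 ways, 7 to 10 of the 10 lower lists were lower and then higher and 2 to 8 (median 5.5) were called both ways, although these lists had been chosen with all 5. The complex I median in TM+NAC against NAC was then 0.322 to 0.606 with NAC 4 on that side and 0.0253 to 0.271 without it.

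The collagen and matrix list was higher (22 of 28 positive, 3 passing and 4 adjusted over the list alone, camera adjusted p = 5.36e-07, and 0.468 as the adjusted p with an estimated correlation). Without the 22 genes that stood apart in TM+NAC, its adjusted p was 0.0714. Copper-dependent enzymes were again called through Lox, 1 of 13 over all genes and adjusted over the list alone (adjusted p = 0.0222, 0.451 without the 22 genes, and 0.468 as the adjusted p with an estimated correlation). Ribosomal proteins were higher (44 of 49 positive, adjusted p = 2.22e-06, and 0.752 as the adjusted p with an estimated correlation), and so were immediate early genes (15 of 21 positive, adjusted p = 0.0315, and 0.753 as the adjusted p with an estimated correlation). Mitochondrial genome transcripts were lower (13 of 13 negative, median -0.233, adjusted p = 0.000995, and 0.752 as the adjusted p with an estimated correlation). No member of the last 3 lists passed over all genes or over the list alone (0 by edgeR).

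With edgeR, 3 genes were higher and 0 lower (1154 at an unadjusted p under 0.05, 496 without NAC 4, and 13 called with no filter), DESeq2 called 5 higher and 3 lower, limma on log2(FPKM + 1) called 6, and only the libraries with brain transcripts gave 4, Lox, Thbs1 and Fn1 with Ttr. Calls on lists were lost without NAC 4 for the mitochondrial genome (adjusted p = 0.28), without NAC 2 for the TCA cycle (0.107), without NAC 2 or 5 for copper-dependent enzymes (0.0896 and 0.0538), without NAC 2 or 5 or TM+NAC 4 for heat shock proteins (0.0896, 0.0593 and 0.172), and without NAC 1, 3, 4 or 5 or TM+NAC 3 or 4 for immediate early genes (0.135, 0.0541, 0.134, 0.0593, 0.0748 and 0.144).

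Between TM+NAC and controls, 30 genes rose and 4 fell. Lox rose from 6.03 ± 2.31 CPM to 43.6 ± 13.8, by 2.85 ± 0.28 (adjusted p = 2.05e-05), and Thbs1 from 6.21 ± 2.91 to 48.6 ± 10.4, by 2.96 ± 0.36 (adjusted p = 0.000276). Fn1 rose by 1.20 ± 0.17 (adjusted p = 0.00142) and Timp1 by 3.23 ± 0.65 (adjusted p = 0.0245), to 3.72 ± 1.75 CPM. Enpp2, the enzyme that makes lysophosphatidic acid, rose by 0.71 ± 0.09 (adjusted p = 0.0005), and it is also on the choroid plexus list, whose sum was 15.7 ± 1.53 CPM in controls and 45.2 ± 2.89 in TM+NAC. That sum holds Enpp2 itself, so it is no separate evidence on this gene. Hmox1 rose from 5.82 ± 1.11 to 8.89 ± 1.11 CPM, by 0.61 ± 0.13 (adjusted p = 0.0302). All 6 were higher in 5 of 5 TM+NAC libraries than in any control.

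Of the 34 called genes, 15 were brain-pattern genes and 5 belonged to the 22 genes of TM+NAC. Of the brain-pattern genes, Kif5a rose by 4.32 ± 0.67 (adjusted p = 0.00302) and Gpm6a by 2.42 ± 0.35 (adjusted p = 0.00142), each in 5 of 5. Outside that pattern, Gpm6b, a membrane protein related to Gpm6a, rose by 1.40 ± 0.22 (adjusted p = 0.00323) and Meg3 by 1.03 ± 0.16 (adjusted p = 0.00302), each in 5 of 5. Ttr, the thyroid hormone carrier made by choroid plexus, was at 16.2 to 20.5 CPM in TM+NAC, at most 5.05 in any other library and at most 0.181 in controls. Gatc, part of a mitochondrial tRNA-modifying complex, fell by 0.41 ± 0.08 (adjusted p = 0.0238, in 5 of 5). Pgc, a stomach pepsinogen, fell in 5 of 5 (adjusted p = 0.0489), to at most 0.196 CPM from controls that ranged from 0.229 to 20.6. Mt2 was at 1.24 ± 0.34 (adjusted p = 0.187, not passing) and the slow-twitch genes Myh7 and Tnnt1 at -0.91 ± 0.40 and -0.89 ± 0.37 (not passing).

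The collagen and matrix list was higher against controls (26 of 28 positive, median 0.267), with 4 passing and 7 adjusted over the list alone (camera adjusted p = 1.1e-22, and 0.244 as the adjusted p with an estimated correlation). Tendon markers were higher (7 of 7 positive, adjusted p = 0.00325, and 0.743 as the adjusted p with an estimated correlation), with the cartilage and tendon protein Comp at 1.45 ± 0.66. These lists stood beside a cartilage gene sum of 53.4 ± 14.2 CPM in TM+NAC and 20.1 ± 6.28 in controls. Nerve markers were higher (9 of 9 positive, adjusted p = 6.24e-09, and 0.302 as the adjusted p with an estimated correlation), beside a neuronal sum of 80.4 CPM. Copper-dependent enzymes were called through Lox, 1 of 13 both ways (adjusted p = 0.00118, 0.352 without the 22 genes, and 0.0842 as the adjusted p with an estimated correlation).

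ER stress genes were higher (20 of 26 positive, camera adjusted p = 0.00156, and 0.14 as the adjusted p with an estimated correlation), with the disulfide oxidase Ero1l at 0.31 ± 0.12. Immediate early genes were higher (19 of 21 positive, adjusted p = 0.000996, and 0.764 as the adjusted p with an estimated correlation). Mitochondrial genome transcripts (13 of 13 negative, median -0.224, adjusted p = 5.66e-05) and antigen presentation (13 of 13 negative, median -0.218, adjusted p = 0.000708) were lower. Both had an adjusted p = 0.743 with an estimated correlation. No member of these 4 lists or of the tendon list passed over all genes or adjusted over the list alone (0 by edgeR).

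The 34 calls (619 at an unadjusted p under 0.05) became 21, 21, 22 and 21 without Control 1, 2 and 4 and TM+NAC 5, 566 with no filter (220 of them brain-pattern genes), 77 with DESeq2, and 8, Lox, Thbs1 and Enpp2 among them, with brain transcripts as a term in the fit. Hmox1 was lost without Control 1, 2, 3 or 5 (adjusted p = 0.103, 0.0961, 0.0647 and 0.0659) or TM+NAC 1, 2 or 5 (0.0626, 0.0791 and 0.14), Timp1 without Control 1 to 5 in turn (0.0748, 0.0547, 0.0703, 0.0815 and 0.0916) or TM+NAC 5 (0.0953), Gatc without Control 1, 2, 4 or 5 (0.078, 0.0712, 0.0893 and 0.06), TM+NAC 2 to 5 in turn (0.0811, 0.0642, 0.102 and 0.0815) or TMM (0.149), Pgc without Control 1, 2 or 5 (0.0814, 0.0986 and 0.122), TM+NAC 1 to 5 in turn (0.138, 0.167, 0.14, 0.127 and 0.167) or TMM (0.0645), tendon markers without Control 4 or TM+NAC 3 (0.11 and 0.174) and immediate early genes without Control 1 (0.155), and the 8 lists became 14 without Control 4.

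Lox was the gene whose fold with TM passed the test of a difference with and without NAC. It is 1 of the 22 genes that stood apart in TM+NAC, beside Col2a1, Saa3 and Xist. A response of the muscle cannot be told apart there from RNA of other cells. The effect of TM on Lox was 2.44 ± 0.38 larger with NAC (adjusted p = 0.0287). Thbs1 at 2.64 ± 0.49 (adjusted p = 0.11) and Fn1 at 1.18 ± 0.24 (adjusted p = 0.287) did not pass with edgeR on all libraries. Hmox1 was at 0.42 ± 0.18, Mt1 at 0.59 ± 0.35, Nmrk2 at -0.89 ± 0.33 and the clock gene Arntl at -0.58 ± 0.22, none passing. The smallest p among negative differences was that of Wdr47 at -0.57 ± 0.14 (adjusted p = 0.597, not passing).

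Complex I had a more positive TM effect with NAC in 34 of 36 members (median 0.386, camera adjusted p = 1.92e-11), ATP synthase in 15 of 16 and complex IV in 22 of 28 (adjusted p = 4.55e-05 each). Complexes II and III had this direction in 13 of 16 (adjusted p = 0.00846), antioxidant enzymes in 24 of 32 (adjusted p = 0.00473) and ribosomal proteins in 48 of 49 (adjusted p = 1.92e-11). These 6 lists had an adjusted p = 0.685 with an estimated correlation. Fatty acid oxidation was called in the same direction (22 of 28, adjusted p = 0.00303, and 0.727 as the adjusted p with an estimated correlation). Mitochondrial genome transcripts had 13 of 13 negative (adjusted p = 0.00389), slow-twitch genes 13 of 17 positive (adjusted p = 0.0313) and collagen and matrix 14 of 28 positive (adjusted p = 0.00404). These 3 had an adjusted p = 0.906 with an estimated correlation. The matrix list had a mean of 0.38 and a median of 0.046, with Lox passing over all genes and 4 members adjusted over the list alone, and its adjusted p was 0.783 without the 22 genes. In the other 9 lists 0 members passed by edgeR over all genes or the list alone. The same NAC libraries enter this difference with a negative sign, and complex I was low in them against controls (median -0.291). Its median was -0.0685 in TM against control and 0.0613 in TM+NAC against TM, where camera did not call it (adjusted p = 0.16). No division of the NAC libraries was made for the interaction.

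Lox was the 1 gene called (706 at an unadjusted p under 0.05, 471 without NAC 4, 7 called with no filter, 9 by DESeq2 and 3 by limma on log2(FPKM + 1)), and it was lost without Control 2, 3 or 5 (adjusted p = 0.0509, 0.0598 and 0.0881), TM 2, 3, 4 or 5 (0.105, 0.0801, 0.0988 and 0.0837), NAC 1, 2 or 5 (0.0677, 0.0669 and 0.0931) or TM+NAC 2 or 5 (0.0611 and 0.0602), each leaving 0 genes, and with the robust variance model (0.0608), while Thbs1 passed without Control 4, TM 1 or NAC 3 (0.0461, 0.0206 and 0.0302) and with quantile normalization, library weights, DESeq2, limma on log2(FPKM + 1) or brain transcripts as a term (0.00088, 0.0237, 0.00279, 0.00209 and 0.0295), Fn1 without Control 4 or TM 1 (0.0461 and 0.0399) and with library weights, DESeq2 or brain transcripts as a term (0.0389, 0.00279 and 0.0295), and the count was 3, 4, 2, 7 and 2 without Control 4, TM 1, NAC 3, NAC 4 and TM+NAC 3. Calls on lists were lost without NAC 4 for the mitochondrial genome (0.188), TM 4 for fatty acid oxidation (0.0575), Control 3 or TM 5 for the matrix (0.0652 and 0.0777), and Control 2 or 4, TM 4, NAC 2 or 4 or TM+NAC 3 or 4 for slow-twitch genes (0.181, 0.0862, 0.573, 0.0752, 0.132, 0.317 and 0.131).

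**Figure D4:**
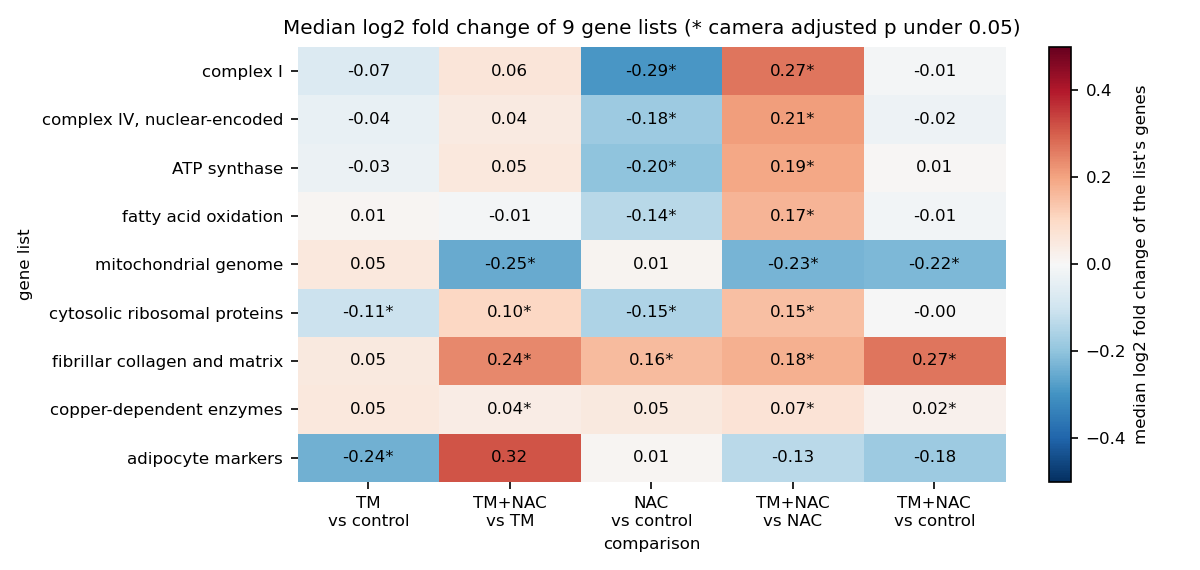
Median log2 fold of the tested members of 9 gene lists (rows) in 5 comparisons (columns), with a star where the camera adjusted p was under 0.05. Complex I had a median of -0.291 in NAC against control and 0.269 in TM+NAC against NAC. With the NAC libraries divided between these comparisons, the medians were -0.112 to -0.219 and 0.0253 to 0.271 where NAC 4 was on the other side.

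Across 9696 genes, the TM effect with NAC and the TM effect without it were nearly uncorrelated (Pearson r = -0.0714, Spearman rho = -0.144, across genes, which are not independent replicates). The value was 0.16 without TM 1 and 0.179 without TM+NAC 5, so its sign rested on single libraries. With no gene changed in any group, simulations gave -0.202 to 0.0886. They drew each gene independently, so their range does not bound chance. Splits of the real libraries reached 0.376 in absolute value. Nmrk2 followed the question of whether NAC returns TM genes toward control, at 149 CPM in TM and 79.9 ± 10.3 in TM+NAC, without passing in either comparison (it passed in both when only the groups compared were fitted, at 0.0367 and 0.0488). Since edgeR called 0 genes in TM against control (327 at an unadjusted p under 0.05, 19 called by DESeq2 and 1 by limma), no called gene could be followed, and the 327 genes were taken instead, a choice made after seeing the data. Of these, 246 (75.2%) had the opposite sign in TM+NAC against TM, and 0 of them passed by edgeR. Because TM enters both comparisons with opposite sign, simulations with no gene changed, again with genes drawn independently, gave 89.9% on average. With the 5 TM libraries divided between the comparisons in 10 ways, the share was 29.9 to 51.1% with a median of 44.2%.

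No gene was called in the same direction in all 3 treated groups by edgeR past the filter (0 genes, but 10 without TM 1 and 194 with no filter). At an unadjusted p under 0.05, 50 genes were higher and 20 lower in all 3 treated groups, and 16 of the 50 and 0 of the 20 were brain-pattern genes. With unchanged genes and shared controls, 20 simulations gave on average 23.6 higher and 14.4 lower, with maxima of 36 and 22. Each gene was drawn independently there, without the correlation between real genes, so these maxima do not bound chance.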

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

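The tests of the brain transcripts and of the TM+NAC genes were chosen after the result was seen, while those of the gene lists lower after NAC and of other splits of the libraries were chosen before.

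Brain transcripts were high in 13 libraries and low in 7. In TM library 1 the neuronal sum was 12.2 CPM (others of its group 54.7 to 65.6) and in NAC library 4 it was 9.32 CPM (others 80.8 to 93.7). RNA or reads from brain stays open as a source: 19 of 20 neuronal genes, none past the filter in controls, were higher in each of the 13 than in any of the 7, which restates a division drawn from a sum that holds them, although the neuronal sum alone gives the same division and 5 of 10 oligodendrocyte and 5 of 12 astrocyte genes, without a part in it, followed it. A response in every treated animal is argued against by 2 treated libraries at or below the highest control, and more peripheral nerve by its log2 ratio of 0.542 ± 0.385 between the 13 and the 7 (8 genes, 2 of them past the filter in controls) against 2.84 ± 0.119 for the neuronal genes. Among genes under the filter, 218 had this pattern, and how brain RNA would have entered was not tested.

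Lox, Thbs1 and Fn1 were high in all TM+NAC libraries together with Col2a1, Saa3 and Xist. In 7 other cartilage genes the median log2 ratio was 0.357 ± 0.408 (SE over genes) against 4.43 for Col2a1. That ratio cannot decide on cartilage in the dissected muscle, since Col11a2, for example, was at 4.25 CPM or more in every library. Added RNA moves the log2 ratio of such a gene less. Cartilage as the whole source of Col2a1 is argued against by 1 gene, Acan. It was at 0.676 CPM or less in TM+NAC and up to 3.24 elsewhere (1 of 15 cartilage genes passed the filter in controls). On the other side, Col11a1 at 5.92 to 9.58 CPM (others at most 4.29) and Cnmd at 0.656 to 1.86 (others at most 0.551) were, with Col2a1, the 3 of 15 that were higher in every TM+NAC library, so a part from cartilage stays open. RNA from other cells in the TM+NAC libraries and a response of the muscle to TM with NAC cannot be told apart: Xist, which male muscle should hardly express, was at least 1.22 CPM in every TM+NAC library (others at most 0.859), and Lox at least 33.7 CPM (others at most 10.6), so no library separates source from group. Among genes under the filter, 17 had this pattern, and of the 13 inflamed stromal genes most were picked from these libraries and none reached the filter in controls. TM+NAC 5 had the highest Lox (67.8 CPM), Thbs1 (65.9) and Fn1 (141) of all libraries, and also the highest Saa3 (14.5) and Xist (3.22). That is 1 library, so it does not decide between other cells and a response of the muscle.

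Gene lists of mitochondrial metabolism were lower after NAC. NAC library 4, with 20.3% of counts from mitochondrial genes (others 13.6 to 15.4%) and 90.7 M counts (others 54.7 to 65.1), is argued against as the sole source, since without it 9 of the 10 lower lists were called. The size of the change did depend on it. With 3 NAC libraries against controls, the complex I median was -0.287 to -0.48 with NAC 4 among them and -0.112 to -0.219 without it. Genes at an unadjusted p under 0.05 went from 721 to 488 without NAC 4, where 485 are expected by chance. A response to NAC stays open: the complex I list was called lower in 10 of 10 settings without 1 library by camera with a preset correlation, but its adjusted p was 0.428 with an estimated correlation, fry called no list, and 24 of 100 splits of the libraries gave as many lists as the 14 observed (highest other 21). Chance therefore cannot be excluded.

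Of 152 groups of values, 27 held a library far from the others of its group. Chance gives about 1 in 20 for independent groups, but these are not independent. Several of the genes are brain-pattern genes, and TM 1 and NAC 4 are among the 7 libraries without brain transcripts. That rate is therefore no reference for the count. In NAC library 4, Meg3 was at 28.2 CPM (others 50.1 to 56.6), Snhg11 at 1.2 (19 to 22.9), Ndrg4 at 1.7 (11.4 to 14.5), Syp at 3.05 (11.4 to 12.3), Nrgn at 1.46 (5.74 to 6.71) and Agap2 at 2.88 (9.53 to 12.2). Ptgds and Ttr were listed at 0 there (others 3.4 to 4.46 and 3.8 to 5.05). In TM library 1, Snhg11 was at 0.574 CPM (11.4 to 14.3), Kif5a at 0.901 (9.94 to 13) and Nrgn at 1.02 (3.98 to 4.81). NAC library 4 also had Mstn at 142 CPM (80.7 to 91.2) and Fn1 at 38.8 (49.8 to 54). Control 4 had Mstn at 121 CPM (57.9 to 74.7) and Mt1 at 11.1 (5.3 to 6.47), and Control 2 had Ccs at 10.1 (7.86 to 8.51). Control 3 had Gpm6b at 8.56 CPM (3.89 to 4.89) and Ptgds at 0.264 (0 in the others). TM+NAC 5 had Lox at 67.8 CPM (33.7 to 39.9) and Mt2 at 8.43 (3.94 to 5.11), and TM+NAC 1 had Agap2 at 8.11 (9.61 to 9.88). TM 5 had Enpp2 at 13.1 CPM (15.8 to 16.1), and NAC 3 had Pgc at 6 (0.128 to 0.253).

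The effect of TM differed with NAC by a log2 value of 2.44 for Lox and, by camera with a preset correlation, in 10 gene lists, whose adjusted p was 0.685 to 0.906 with an estimated correlation and none of which fry called. By gene counts, as many as observed came from 1 of 100 splits for TM+NAC against TM (3 genes, highest other 1), from 1 for TM+NAC against NAC (3, highest other 0) and from 1 for TM+NAC against control (34, highest other 1). That 1 is the real split in each case. Chance is argued against there as the source of these counts, as far as 100 splits of libraries taken as independent can show. It cannot be excluded for NAC against control (21 genes, 6 splits, highest other 502) or the interaction (1 gene, 5 splits, highest other 2). For TM against control the count was 0 (by edgeR, 327 at an unadjusted p under 0.05, 19 by DESeq2 and 1 by limma), which 100 of 100 splits reach by construction (highest other 7), so the splits decide nothing there. The split with 502 genes, Control 1, 2 and 5 with NAC 2 and 5 against the rest, points to a structure of the samples. For gene lists chance cannot be excluded in TM against control (4 lists, 97 splits, highest other 23), TM+NAC against TM (8, 80 splits, 22), TM+NAC against NAC (13, 17 splits, 17), TM+NAC against control (8, 82 splits, 24) or the interaction (10, 60 splits, 21). Nor can it be for the correlation of the TM effects (-0.0714, 70 splits, highest other 0.376).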

How the results depend on the processing

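DESeq2, limma on log2(FPKM + 1), no TMM, the division of the NAC libraries, the settings on brain transcripts and, for gene lists, no filter and leaving out libraries were chosen after seeing the data, the others before the data were examined. Gene counts with all libraries were 0 in TM against control (by edgeR, 327 at an unadjusted p under 0.05), 3 in TM+NAC against TM, 21 in NAC against control, 3 in TM+NAC against NAC, 34 in TM+NAC against control and 1 in the interaction, and lists 4, 8, 14, 13, 8 and 10. Below, counts follow this order, and the cause of each change was not tested unless given. Without 1 library at a time, gene counts ran from 0 to 12, 3 to 4, 4 to 41, 3 to 4, 21 to 33 and 0 to 7, and list counts from 3 to 13, 6 to 12, 11 to 16, 10 to 18, 8 to 14 and 8 to 13. The correlation of the TM effects ran from -0.27 to 0.179 (reversed at 0.16 without TM 1 and 0.179 without TM+NAC 5), genes called in all 3 treated groups from 0 to 10 and genes reversed by NAC stayed at 0. DESeq2 called 19, 19, 38, 8, 77 and 9 genes. Library weights gave 2, 10, 34, 5, 66 and 6 genes and 1 in all 3 treated groups. With no filter there were 197, 21, 439, 13, 566 and 7 genes, 194 in all 3 treated groups, and 14, 9, 22 and 21 lists in TM+NAC against TM, NAC against control, TM+NAC against NAC and the interaction. A mean FPKM of at least 5 tests fewer genes and leaves out Lox, Thbs1, Fn1 and the genes named as rising after NAC. The genes called between TM+NAC and TM or NAC could therefore not be called again. This filter gave 2, 0, 0, 0, 0 and 0 genes and 7, 5 and 6 lists in TM+NAC against NAC, TM+NAC against control and the interaction. There the copper-dependent enzymes reversed (adjusted p = 0.211 against TM, 0.813 against NAC and 0.934 against control). Gene counts were 1, 6, 3 and 5 in the first 4 comparisons with log2(FPKM + 0.1), and 1, 6, 2, 6 and, in the interaction, 3 with log2(FPKM + 1). Quantile normalization gave 2, 6, 6 and 3 in TM against control, TM+NAC against TM, TM+NAC against NAC and the interaction. Only the groups compared gave 2, 9, 0 and 57 in TM against control, TM+NAC against TM, NAC against control and TM+NAC against control, and 1 gene reversed by NAC. The robust model gave 0 in the interaction (Lox at an adjusted p of 0.0608). The replicate number as a block gave 10 in NAC against control and 0 in the interaction (Lox at 0.0604), and numbers do not pair the libraries: 13 of 30 same-numbered pairs had r over 0.1 (median 0.0303 against -0.0158 for other numbers). The exact rank-sum test gave 0 in the 4 comparisons of groups with calls (lowest adjusted p 0.347, 0.534, 0.304 and 0.153), which shows nothing, since its smallest p with 5 against 5 libraries is 0.00794 and 1540 of 9696 genes would have to reach it, and it was not run on the interaction. Brain transcripts as a term, which rests on TM 1 and NAC 4 alone, gave 1, 7, 2322, 8 and 1339 genes in TM against control, TM+NAC against TM, NAC against control, TM+NAC against control and the interaction, 8 lists in NAC against control and 1 gene in all 3 treated groups. With it, nerve markers in NAC against control (adjusted p = 0.787), immediate early genes in TM against control (0.998) and the mitochondrial genome in TM+NAC against control (0.196) reversed, as did Ttr (-2.66) and Kif5a (-0.001542) in TM+NAC against control. The collagen list in NAC against control ran from 1.59e-05 (without NAC 4) to 0.865 (without Control 4, where it reversed). Only the libraries with brain transcripts gave 9 genes in TM+NAC against TM. No list was called (0) in any comparison with an estimated correlation or with fry. Over all settings, of the values for named genes 4173 kept sign and side of the threshold, 83 gained and 161 lost the call with the same sign (29 of them in the rank-sum test), 2 reversed, and 129 changed sign without a call in either fit, and of those for lists 1105 kept both, 257 lost the call and 7 reversed. Without TMM the median log2 fold of all genes reached 0.0821, in TM+NAC against TM (0.00211 with TMM). With log2(FPKM + 0.1) it reached 0.114, in TM+NAC against control (-0.00591 in the edgeR fit with TMM). Depth limits the low genes: at the median depth 3 counts are under 1 CPM.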

Other observations

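Clock genes went in both directions between TM+NAC and TM, and none passed over all genes with edgeR on all libraries: Arntl was at -0.71 ± 0.15 (adjusted p = 0.184, and 0.006 with DESeq2), Nr1d1 at -0.49 ± 0.14 (0.463, but 0.0371 with only the groups compared, 0.0417 with library weights and 0.00356 with only the libraries with brain transcripts), Dbp at 0.70 ± 0.21 (0.635) and Per2 at 0.98 ± 0.32 (0.69). Adjusted over the list alone, 2 members passed as higher and 2 as lower. The circadian list was not called as moving 1 way (camera adjusted p = 0.349, and 0.821 as the adjusted p with an estimated correlation), and it was called by fry's test for change in either direction (adjusted p = 0.0119), as were 4 lists in all in this comparison.

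Summed levels of other lists, in controls, TM, NAC and TM+NAC, were as follows. Astrocyte genes (12, of which 2 were past the filter in controls) were at 76.5 ± 6.02, 92.3 ± 13.9, 96.8 ± 6.17 and 98.8 ± 5.39 CPM, and oligodendrocyte genes (10, none past it) at 3.08 ± 2.25, 7.57 ± 3.48, 10.6 ± 4.53 and 14 ± 2.02. Choroid plexus genes (12, 1 past it) were at 15.7 ± 1.53, 20.9 ± 2.28, 24.6 ± 1.44 and 45.2 ± 2.89 CPM. Peripheral nerve genes were at 110 ± 88.7, 96.6 ± 58.6, 116 ± 51.7 and 161 ± 69.8 CPM, cartilage genes at 20.1 ± 6.28, 22.5 ± 9.84, 24.3 ± 14.5 and 53.4 ± 14.2, and inflamed stromal genes at means of 6.11, 4.64, 6.14 and 43.9. Mean levels of liver genes (8, 1 past it) were 15.2, 8.63, 17.9 and 13.5 CPM, of heart genes (7, 2 past it) 18.8, 14.6, 15.2 and 14.1, of kidney genes 0.0877, 0.0418, 0.0272 and 0.119, of lung genes 0.194, 0.22, 0.109 and 0.134, and of testis genes 0.0274, 0.0349, 0.0533 and 0.0408. Atp7a, the copper exporter, lay under the filter at 2.8 ± 1.09, 2.63 ± 0.77, 3.27 ± 1.29 and 3.15 ± 0.674 CPM.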
